A study of Drosophila melanogaster with 8 samples.

How the data were processed

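Gene expression was measured in S2 cells, a macrophage-like Drosophila melanogaster cell line, on 8 arrays with total RNA labelled with biotin by an Affymetrix 3' IVT kit, per the labels' protocols. Cells received double-stranded RNA, either a scrambled sequence or one against the DmSTING transcript, and 72 h later were transfected with cyclic di-GMP (c-di-GMP, a bacterial second messenger) or were mock transfected with the lipid reagent alone. RNA was taken 24 h after that. The 4 groups held 2 samples each. They were assigned from the sample titles, which the source names bear out, whereas the genotype field contradicts both in 4 samples and follows the treatment instead. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

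The values are the table of log2 expression deposited by the authors, with 16718 probe sets and 8 columns. Each of the 16718 probe sets had a median over the 8 samples within 1e-06 of 0, so the deposited values are relative to each probe set's own median and no expression level remains. The summarization of probes, the scaling between arrays, any filter and the software are not given in the sources used here. The base of the logarithm is not stated either and was taken as 2; the folds and percentages given depend on that choice. That a higher value means more transcript is also not stated; the Sting transcript, lower after DmSTING dsRNA, goes with it. Column medians of the log2 values were 0.0006 and 0.0079 for scrambled mock, -0.0225 and -0.0043 for scrambled c-di-GMP, 0.0027 and 0.007 for DmSTING RNAi mock, and -0.0014 and -0.001 for DmSTING RNAi c-di-GMP, for replicates 1 and 2 in that order. No replicate pair had identical values. The number of arrays limits the precision, and signal over background cannot be read from centred values.

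Probe sets were named from a platform annotation, and its symbols were checked through Entrez ID against a RefSeq gene table; 0 symbols needed updating and 74 IDs were not found in that table. Of the probe sets, 12338 had 1 gene symbol, 367 had several, 3889 had none and 124 were controls. Only single-gene probe sets entered the tests of genes, which covered 11009 genes, 920 of them with more than 1 probe set. The plan took the probe set with the highest mean of each gene; with centred values that mean carries no level, so the probe sets of a gene were averaged instead, which the plan had named as a second choice. No genome build is given for the values, and no coordinates are printed.

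The 11009 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) in a model of the 4 group means, with all 8 samples sharing 1 estimate of the spread per gene on 4 residual degrees of freedom. The prior had 3.25 degrees of freedom and an SD of 0.0902 on the log2 scale. There were 7 contrasts: c-di-GMP against mock in each RNAi arm, the difference of those responses (interaction, DmSTING RNAi minus scrambled), DmSTING RNAi against scrambled under mock and under c-di-GMP, and the average effect of each factor. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, and an adjusted p under 0.05 is called. Adjusted p-values of genes throughout come from this model. Errors of log2 changes are its standard errors (SE) with n = 2 per group.

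There were 25 gene lists, fixed like the groups, contrasts, thresholds and naming rule before the data were examined. They were IMD-dependent antimicrobial peptides, Toll-dependent effectors, IMD pathway components and regulators, Toll pathway components, JAK-STAT pathway and targets, STING-linked antiviral genes, small RNA machinery, JNK pathway and targets, heat shock response, unfolded protein response, detoxification and oxidative stress, lipid synthesis and storage, autophagy, apoptosis, purine nucleotide synthesis, DNA replication and cell cycle, ribosome biogenesis, cytosolic ribosomal proteins, ecdysone response, and markers of plasmatocytes, crystal cells, lamellocytes, fat body, neurons and muscle. Many members were left out because their probe sets name several genes or none; of the antimicrobial peptide list 6 of 14 members were measured. The lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a contrast, and again with camera at an estimated correlation and with fry. Fry tests whether the members of a list move, on balance, one way, without comparing them with other genes.

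Genes named in the text follow a rule fixed in advance. For each contrast it takes the 10 called genes highest and the 10 lowest in log2 change, and where a direction has fewer, fills it up to 5 with genes of smallest unadjusted p and an absolute log2 change of at least 0.5. It adds Sting, and from each list up to 4 called members with the largest change, or the 2 of smallest p where none was called. AttD and edin are named outside this rule, as are the values of Def, CecB and DptB in the scrambled arm and the values that a gene named for a comparison had in another; these were chosen after their values were seen. Making the antimicrobial peptide list a result of its own, a signed test of the interaction over all responding genes, the lists of RNA polymerase III and vacuolar ATPase subunits, robust eBayes, the overlap of the arms from separate fits, the set tests of antimicrobial peptides with an estimated correlation and with fry without a replicate, and the control probe set described at the end were also chosen after the data had been examined.

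The procedure was tested on simulated data, normal noise drawn with the fitted prior spread, with 67, 67 and 66 changed genes of 3 sizes among 11009. Of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 52.2%, 91% and 100% for c-di-GMP against mock in scrambled RNAi, 49.3%, 89.6% and 93.9% in DmSTING RNAi, 19.4%, 86.6% and 100% for the interaction, 46.3%, 92.5% and 98.5% for DmSTING RNAi against scrambled under mock, and 46.3%, 91% and 100% under c-di-GMP. Unchanged genes made up 3.6%, 5.5%, 7.4%, 4.8% and 3.7% of the calls in that order. The simulated genes were independent and had the same spread in every group. In the data the SD of the difference between replicates ran from 0.119 to 0.233 by group. The rates therefore do not tell which changes would be called here: the interaction of Mtk, at -1.61, had a limma adjusted p of 0.988. Alternatives were quantile normalization, centring each array on its median, the replicate number as a block, robust eBayes, the highest-mean probe set, all probe sets other than controls, fits of only the groups compared, other thresholds, and leaving out each sample in turn. Also named in advance, a filter on dim probe sets, eBayes with a trend and a pseudocount were not run, since the first and second of these need an expression level and the values are already logarithms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 for the annotation.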

Results

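RNA of S2 cells, a macrophage-like Drosophila melanogaster line derived from embryos, was measured on 8 arrays in 4 groups of 2 samples. The groups were scrambled dsRNA with mock transfection, scrambled dsRNA with c-di-GMP, DmSTING dsRNA with mock transfection and DmSTING dsRNA with c-di-GMP. The study asked how DmSTING, the fly homologue of the cyclic dinucleotide sensor STING, affects the response to c-di-GMP. Values are log2 units relative to each probe set's median over the 8 samples, so differences between groups can be read and expression levels cannot. Between the replicates of a group, the SD of the difference over genes was 0.166 for scrambled mock, 0.233 for scrambled c-di-GMP, 0.119 for DmSTING RNAi mock and 0.196 for DmSTING RNAi c-di-GMP. With 2 arrays per group, their number limits the precision, and whether the replicates were separate cultures is not given.

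The Sting transcript (CG1667) was lower in all 4 samples given DmSTING dsRNA than in all 4 given the scrambled sequence. Its log2 values were 0.81 and 0.83 in scrambled mock, 0.57 and 0.46 in scrambled c-di-GMP, -0.48 and -0.46 in DmSTING RNAi mock, and -0.84 and -0.75 in DmSTING RNAi c-di-GMP. On average over both treatments it fell by 1.3 on the log2 scale (SE 0.05, n = 2 per group, limma adjusted p = 0.000252), which leaves 40.6% if the base of the logarithm is 2. Sting also fell with c-di-GMP, with a log2 change of -0.31 in the scrambled arm (adjusted p = 0.0366) and -0.33 in the DmSTING RNAi arm (adjusted p = 0.0376). For either arm, leaving out a library of the other arm alters only the estimate of spread, not the log2 change. The call in the scrambled arm was lost without any 1 of 5 libraries, namely either scrambled mock, scrambled c-di-GMP replicate 2 or either DmSTING RNAi mock (adjusted p from 0.0879 to 0.146). The call in the DmSTING RNAi arm was lost without any library other than the scrambled c-di-GMP replicates (adjusted p from 0.0659 to 0.244) and after quantile normalization the change was 0.01.

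**Figure D1:**
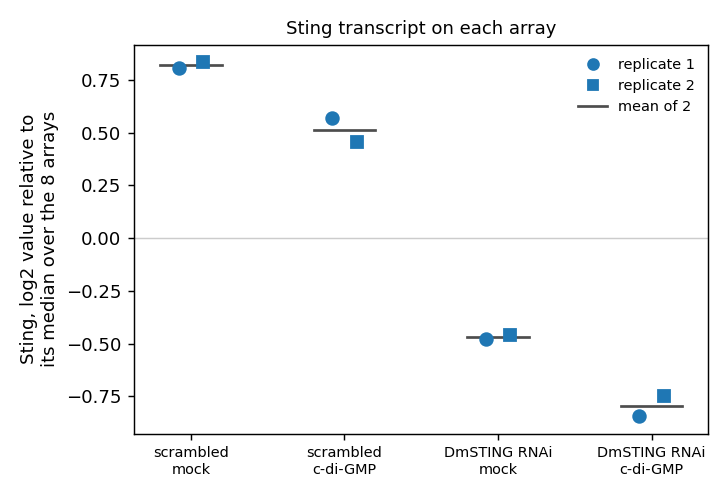
Sting transcript in each of the 8 samples, as log2 value relative to the median of its probe set, by group. The samples given scrambled dsRNA lie between 0.46 and 0.83, and those given DmSTING dsRNA between -0.84 and -0.46.

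In cells given scrambled dsRNA, c-di-GMP raised Mtk, Tsf1, Listericin and Nazo. Mtk, the antimicrobial peptide metchnikowin, rose by 2.42 on the log2 scale (SE 0.43, n = 2 per group, 5.34-fold, adjusted p = 0.0162). Tsf1, a transferrin, rose by 1.71 (SE 0.33, adjusted p = 0.0214), Listericin, an antibacterial peptide, by 1.29 (SE 0.28, adjusted p = 0.0274), and Nazo, an antiviral gene downstream of Sting, by 1.02 (SE 0.19, adjusted p = 0.0173). All 4 calls were lost without either scrambled mock replicate (adjusted p = 0.0742 and 0.0959 for Mtk, 0.0635 and 0.106 for Nazo, and from 0.0997 to 0.122 for the others), and those of Tsf1 and Listericin after quantile normalization (1.12, adjusted p = 0.0562, and 0.92, adjusted p = 0.0615). That of Tsf1 was also lost without scrambled c-di-GMP replicate 1 (adjusted p = 0.0622), and that of Listericin without either scrambled c-di-GMP or either DmSTING RNAi mock replicate (adjusted p from 0.0589 to 0.0646). Of the 6 measured IMD-dependent antimicrobial peptides, 1 rose over all genes and 5 when adjusted over the list alone. Their median change was 1.45, with Def at 1.91, CecB at 1.83, AttD at 1.07, edin at 0.82 and DptB at 0.31. Without either DmSTING RNAi c-di-GMP replicate, Def (SE 0.16, adjusted p = 0.00708) and CecB (SE 0.21, adjusted p = 0.0102) were called over all genes. The list was called by camera (adjusted p = 0.00118), and the call was lost with an adjusted p = 0.403 with an estimated correlation and 0.119 by fry. After quantile normalization the median was 0.94 (adjusted p = 0.00522).

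The other genes highest after c-di-GMP in the scrambled arm were CG8519, at a log2 change of 2.65 (SE 0.52, adjusted p = 0.021), CG32373 at 2.33, CG34165 at 1.91, CG34227 and CG43109 at 1.77, Tret1-1, a trehalose transporter, at 1.67 (SE 0.09, 3.17-fold, adjusted p = 0.00219), and CG12520 at 1.34. The lowest was btn, a homeodomain transcription factor, which fell by 2.46 (SE 0.15, 5.51-fold, adjusted p = 0.00219). CG6770 changed by -2.16, CAH1, a carbonic anhydrase, by -1.79, Drat by -1.72, esg, a Snail-family transcription factor, by -1.69 (SE 0.41, adjusted p = 0.0399), and Gs1, a glutamine synthetase, by -1.5. BNIP3, a mitophagy receptor, changed by -1.45, mlt by -1.41, dnr1, a negative regulator of the IMD pathway, by -1.37 (SE 0.09, adjusted p = 0.00219) and bam, a germline differentiation factor, by -1.37. Without either scrambled mock replicate the calls of CG8519, CG32373, CG34165, CG34227, CG43109, esg and bam were lost (adjusted p from 0.0793 to 0.187), and that of Gs1 without replicate 2 (adjusted p = 0.0586). After quantile normalization CG8519 was at 1.69 (adjusted p = 0.0721), CG34165 at 1.28 (adjusted p = 0.0557) and CG43109 at 1.15 (adjusted p = 0.109), none called. Calls were also lost without scrambled c-di-GMP replicate 1 (CG32373, CG43109 and esg), without its replicate 2 (CG8519, CG32373, CG34165 and CG43109) and without either DmSTING RNAi mock replicate (CG34165, CG43109 and esg), with an adjusted p from 0.0502 to 0.109.

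Ribosome biogenesis genes rose together in the scrambled arm. Of 18 measured members 14 rose, both over all genes and adjusted over the list alone, with a median of 0.48 (camera adjusted p = 8.27e-13; adjusted p = 0.0553 with an estimated correlation). Examples were CG13185 at 0.96, CG1542 at 0.68, Nnp-1 at 0.66 and Nop60B, the pseudouridine synthase of rRNA, at 0.64. Lipid synthesis and storage genes fell, 8 of 14 over all genes and 9 adjusted over the list alone, where 1 rose (median -0.39, camera adjusted p = 0.00118; adjusted p = 0.371 with an estimated correlation). Among them were the perilipin Lsd-1 at -0.82, the acetyl-CoA synthetase AcCoAS at -0.66, the lipase bmm at -0.58 and the fatty acid synthase FASN1 at -0.54. Autophagy genes fell, 8 of 16 and 9 adjusted over the list alone (median -0.28, camera adjusted p = 0.00772; adjusted p = 0.371 with an estimated correlation). Atg9 was at -0.61, Atg18a and Atg8a at -0.46 and Pi3K59F at -0.37. Of 14 genes of DNA replication and cell cycle 3 fell, and 8 fell and 1 rose adjusted over the list alone (median -0.25, camera adjusted p = 0.0039; adjusted p = 0.403 with an estimated correlation). Orc1 was at -0.51, Mcm2 at -0.44 and Mcm5 at -0.33. Of 6 heat shock genes 4 fell on both adjustments (median -0.66, camera adjusted p = 0.0249; adjusted p = 0.403 with an estimated correlation). These were Hsp68 at -0.76, Hsp27 at -0.69, Hsp26 at -0.68 and the co-chaperone stv at -0.64.

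Camera also called smaller shifts in other lists. Of 9 genes of the small RNA machinery 1 rose on both adjustments, vig at 0.45 (median 0.11, adjusted p = 0.0107; adjusted p = 0.371 with an estimated correlation). Of 17 genes of detoxification and oxidative stress 3 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (median 0.09, adjusted p = 0.0487; adjusted p = 0.436 with an estimated correlation). They were the glutathione transferases GstD2 at 0.84, GstD5 at 0.31 and GstD3 at 0.3, and catalase, Cat, at -0.62. Of 8 neuronal markers none passed on either adjustment (median 0.16, adjusted p = 0.0372; adjusted p = 0.371 with an estimated correlation), brp being at 0.21 and elav at 0.19. The call for DNA replication and for small RNA machinery ended without scrambled c-di-GMP replicate 2. That for heat shock ended without scrambled mock replicate 1 or scrambled c-di-GMP replicate 2, that for detoxification without either scrambled mock replicate or scrambled c-di-GMP replicate 2 and with the highest-mean probe set, and that for neuronal markers without scrambled mock replicate 2 or scrambled c-di-GMP replicate 1 and with quantile normalization.

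Camera did not call the remaining 16 lists in the scrambled arm, and the adjusted p given with each median is from camera. Fry, which does not compare a list with other genes, called 4 of them: Toll pathway components (adjusted p = 0.0279, lower), JAK-STAT genes (adjusted p = 0.0278, lower), the unfolded protein response (adjusted p = 0.0322, higher) and plasmatocyte markers (adjusted p = 0.0279, lower). Toll-dependent effectors had a median of 0.12 (adjusted p = 0.164), with BomT2 at 0.34 and Drs at 1.08, neither past the threshold with all samples. Drs was called without either DmSTING RNAi c-di-GMP replicate (SE 0.18 in place of 0.55, adjusted p = 0.0211). IMD pathway components had a median of -0.06 and a mean of 0.2 (adjusted p = 0.766), with Diap2, a ubiquitin ligase, falling by 0.38 and IKKbeta by 0.28. Adjusted over the list alone 1 member rose and 2 fell, and the largest change was that of PGRP-LB, an amidase that degrades peptidoglycan, at 2.62 (SE 0.7, adjusted p = 0.0527 over all genes), called without either DmSTING RNAi c-di-GMP replicate (adjusted p = 0.000946). Toll pathway components had a median of -0.22 (adjusted p = 0.107), with the serine protease grass falling by 0.64, and JAK-STAT genes -0.1 (adjusted p = 0.164), with vir-1 falling by 0.74. STING-linked antiviral genes had a median of -0.17 (adjusted p = 0.521), as Nazo rose while Sting and IKKbeta fell. JNK genes stood at -0.05, although the test pointed up (adjusted p = 0.863), with the TNF ligand egr at -0.65 and Gadd45 at 0.48, both past the threshold. The unfolded protein response stood at 0.06 (adjusted p = 0.0611), with the eIF2alpha kinase PEK rising by 0.31, and apoptosis at -0.12 (adjusted p = 0.27), with the caspase Dcp-1 falling by 0.36. Purine synthesis stood at 0.02 (adjusted p = 0.401), with Adss at 0.25 and bur at 0.31 short of the threshold. The list of cytosolic ribosomal proteins, whose members were taken by the form of their symbol alone, stood at -0.05 over 41 members (adjusted p = 0.491). RpLP0-like, a member only by that rule, rose by 0.52, and RpL34a fell by 0.33. The ecdysone response stood at 0 with a mean of -0.02, while the test pointed up (adjusted p = 0.521), MsrA falling by 0.78 and the insulin antagonist ImpL2 rising by 0.45. Plasmatocyte markers stood at -0.15 (adjusted p = 0.115), of which 3 of 13 fell: the collagen IV genes vkg by 0.74 and Col4a1 by 0.61, and the phagocytosis receptor NimC1 by 0.64. Crystal cell markers stood at -0.09 (adjusted p = 0.799), lamellocyte markers at -0.23 (adjusted p = 0.168, with PPO3 falling by 0.57 and mys by 0.35), fat body markers at -0.07 (adjusted p = 0.928) and muscle markers at 0.06 (adjusted p = 0.607).

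Over all 11009 genes, 1331 were called in the scrambled arm, 456 higher and 875 lower, of which 16 and 29 changed at least 2-fold. Leaving out DmSTING RNAi libraries, or fitting only the 4 libraries compared, alters the estimate of spread here but not the log2 changes. The count was 427 and 223 without scrambled mock replicates 1 and 2, 587 without either DmSTING RNAi mock replicate, and 142 when only the 4 libraries compared were fitted. Of the 63 calls of genes named for this comparison, 30 and 39 were lost without scrambled mock replicates 1 and 2 (Mtk, Tsf1, Listericin, Nazo, CG8519 and esg in both cases). Those lost were 16 and 17 without scrambled c-di-GMP replicates 1 and 2, 21 without either DmSTING RNAi mock replicate, 6 without either DmSTING RNAi c-di-GMP replicate, and 18 with quantile normalization, which left 885 of the 1331 called. Beyond those already given, the calls lost with quantile normalization were those of IKKbeta, egr, Hsp27, Hsp26, PEK, GstD5, Pi3K59F, Dcp-1, Mcm5, RpL34a, MsrA, NimC1 and mys. The balance of directions moved as well, to 392 higher and 515 lower with quantile normalization. It became more even without scrambled c-di-GMP replicate 1 and moved further towards lower calls without replicate 2.

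In cells given DmSTING dsRNA, Tret1-1 was the gene that rose most with c-di-GMP and btn the one that fell most. Tret1-1 rose by 1.47 on the log2 scale (SE 0.09, n = 2 per group, adjusted p = 0.00211), CG3348 by 1.39 (SE 0.08), Tdh, threonine dehydrogenase, by 1.2 (SE 0.1), Ugt302K1, a UDP-glycosyltransferase, by 1.17, CG13185 by 1.02, and eIF6, a biogenesis factor of the large ribosomal subunit, by 0.89 (SE 0.07). MFS14 at 0.92, CG6908 at 0.91, and CG11563 and Mat89Ba at 0.89 also rose. The gene btn fell by 1.94 (SE 0.15, adjusted p = 0.00337), and the carbonic anhydrases CAH1 and CAH2 changed by -1.76 and -1.74 (SE 0.26 for CAH2). Drat and CG6770 changed by -1.66, mlt by -1.58, Gs1 by -1.57, BNIP3 by -1.52, dnr1 by -1.48 (SE 0.09) and CG11658 by -1.46. Mtk was at 0.81 (SE 0.43, adjusted p = 0.351), CecB at 0.79 (adjusted p = 0.514) and Nazo at 0.68 (adjusted p = 0.0786), none past the threshold. These are means of replicates that differed. Without DmSTING RNAi c-di-GMP replicate 1 Mtk was at 1.61, CecB at 1.83 and Nazo at 0.98, and without replicate 2 they were at 0.01, -0.25 and 0.38. Each of these values rests on the 1 sample left in that group.

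Ribosome biogenesis genes rose in the DmSTING RNAi arm as well, 14 of 18, and 16 rose and 1 fell adjusted over the list alone (median 0.54, camera adjusted p = 8.49e-17, still called with an adjusted p = 0.0329 with an estimated correlation). CG1542 was at 0.8, l(3)72Dn at 0.67 and Nop60B at 0.66. Lipid genes fell, 5 of 14 and 9 adjusted over the list alone (median -0.33, camera adjusted p = 0.00022; adjusted p = 0.225 with an estimated correlation). Lsd-1 was at -0.7, FASN1 at -0.56, AcCoAS at -0.53 and bmm at -0.47. Autophagy genes fell, 6 of 16 and 10 adjusted over the list alone (median -0.24, camera adjusted p = 0.00022; adjusted p = 0.225 with an estimated correlation). Atg7 was at -0.48, Atg8a at -0.46, Atg18a at -0.45 and Atg9 at -0.39. Of 14 replication and cell cycle genes 3 fell, and 8 adjusted over the list alone (median -0.23, camera adjusted p = 0.00022; adjusted p = 0.469 with an estimated correlation). Mcm2 was at -0.43, CycE at -0.41 and Mcm5 at -0.37. Of 6 heat shock genes 2 fell, Hsp68 at -0.67 and stv at -0.59, and 4 adjusted over the list alone (median -0.49, camera adjusted p = 0.00923; adjusted p = 0.505 with an estimated correlation). Of 17 detoxification genes 4 rose and 1 fell on both adjustments (median 0.16, camera adjusted p = 0.000779; adjusted p = 0.478 with an estimated correlation). Among them were GstD5 at 0.7, GstD2 at 0.69, GstD3 at 0.41 and Cat at -0.48.

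The antimicrobial peptide list was not called in the DmSTING RNAi arm, at a median of 0.18 (adjusted p = 0.376; adjusted p = 0.804 with an estimated correlation), with 0 of 6 members past the threshold on either adjustment. That median was 0.99 without DmSTING RNAi c-di-GMP replicate 1 and -0.32 without replicate 2, each resting on the 1 sample left in that group. The other 18 lists had adjusted p between 0.0715 and 0.852; Toll-dependent effectors (median -0.04), JNK genes (-0.01) and cytosolic ribosomal proteins (-0.02) had a median below 0 while the test pointed up. Among their members Diap2 at -0.59, IKKbeta at -0.29, grass at -0.56, GNBP3 at -0.27, egr at -0.62, Dcp-1 at -0.37, vig at 0.49, Fmr1 at 0.35, p53 at 0.37, RpLP0-like at 0.68 and ImpL2 at 0.37 passed.

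Over all genes, 820 were called in the DmSTING RNAi arm, 360 higher and 460 lower, of which 5 and 16 changed at least 2-fold. The excess of lower calls was not stable: without DmSTING RNAi c-di-GMP replicate 1, higher calls outnumbered lower ones. Without DmSTING RNAi mock replicates 1 and 2 limma called 0 in each case, with 1475 and 1524 genes at an unadjusted p under 0.05. The count was 301 and 163 without DmSTING RNAi c-di-GMP replicates 1 and 2, and 1296 after quantile normalization. Of the 52 calls of genes named for this comparison, all 52 were lost without either DmSTING RNAi mock replicate, 23 and 27 without DmSTING RNAi c-di-GMP replicates 1 and 2, and 7 without either scrambled mock replicate.

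The responses of the arms, which share no library, resembled each other. Of the genes called higher after c-di-GMP, 279 were shared by both arms, and of those lower, 379. Both arms use the same estimate of spread per gene there, so independent calls are no baseline for these counts. With each arm fitted on its own 4 libraries, 40 of the 62 genes called higher in the scrambled arm were among the 339 of the DmSTING RNAi arm, where 1.91 would be if the calls were independent. Of the 80 lower, 67 were among 480, where 3.49 would be. Of the scrambled calls, 97.6% of those higher and 96.5% of those lower had the same sign in DmSTING RNAi. Across the 11009 genes Pearson's r was 0.725 and Spearman's rho 0.632, genes not being independent replicates. A single gene, CG18234, was called in opposite directions, at 0.43 in the scrambled arm (adjusted p = 0.0292) and -0.42 in the DmSTING RNAi arm (adjusted p = 0.0388); its interaction had an adjusted p of 0.988.

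**Figure D2:**
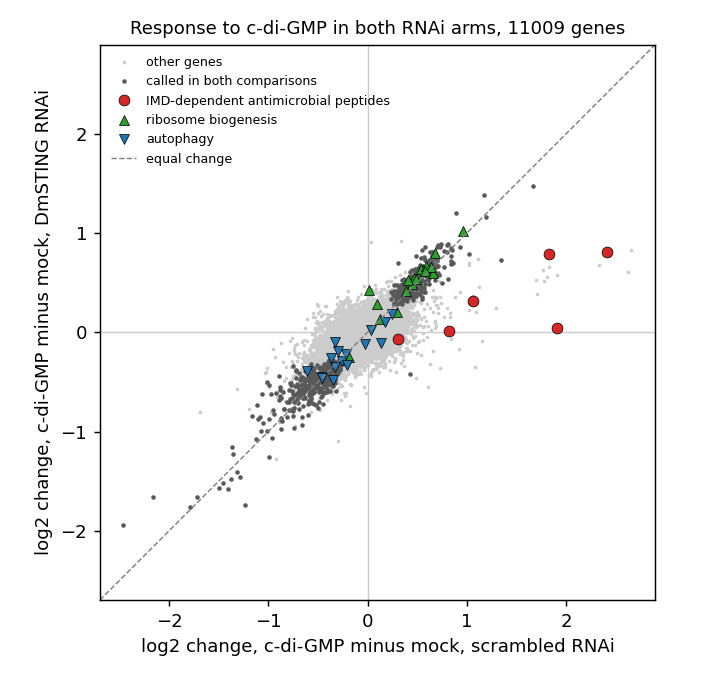
Log2 change with c-di-GMP of each of the 11009 genes in the scrambled arm (x axis) and in the DmSTING RNAi arm (y axis), 1 point per gene. The points lie along the diagonal (r = 0.725), btn being at -2.46 and -1.94, while Mtk lies at 2.42 and 0.81.

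The interaction asked directly whether c-di-GMP acted differently after DmSTING RNAi. The antimicrobial peptide list had the lower response in DmSTING RNAi, with a median difference of -0.92 on the log2 scale and all 6 members negative: Mtk stood at -1.61 (SE 0.61, n = 2 per group) and Def at -1.87 (SE 0.84). In the IMD pathway PGRP-LB stood at -2.02 (SE 0.99) and Rel, the NF-kappaB factor of the pathway, at -0.7 (SE 0.35), and Drs stood at -1.43 (SE 0.77); all of these had an adjusted p of 0.988. Camera called the list (adjusted p = 0.000356), but not with an adjusted p = 0.768 with an estimated correlation or 0.727 by fry, and 0 of its members passed on either adjustment. The difference was -0.25 without DmSTING RNAi c-di-GMP replicate 1 and -1.71 without replicate 2, each resting on the 1 sample left in that group. After quantile normalization it was -0.51 (camera adjusted p = 0.0435).

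The replicates of DmSTING RNAi c-di-GMP differed in these genes. As change from the mean of the same arm's mock samples, the list median was 1.417 and 1.479 in the scrambled c-di-GMP replicates, -0.325 in DmSTING RNAi c-di-GMP replicate 1, where 1 of 6 members lay above mock, and 0.993 in replicate 2, where all 6 did. Mtk stood at 2.48 and 2.35, then 0.01 and 1.61, and Rel at 0.29 and 0.44, then -0.78 and 0.11. PGRP-LB stood at 2.55 and 2.7, then -0.71 and 1.93, Def at 1.7 and 2.12, then -1.05 and 1.14, and Drs at 0.87 and 1.3, then -1.34 and 0.64. Without DmSTING RNAi c-di-GMP replicate 1 the interaction was -0.81 for Mtk, -0.77 for Def, -0.69 for PGRP-LB, -0.26 for Rel and -0.44 for Drs. Without replicate 2 it was -2.41 for Mtk, -2.96 for Def, -3.34 for PGRP-LB, -1.15 for Rel and -2.43 for Drs. Each of these fits rests on 1 sample of that group and takes its spread from the other groups. For PGRP-LB the SE fell from 0.99 to 0.14 in either fit, although the replicates stood at -0.71 and 1.93. The ribosome biogenesis median was alike in all 4, at 0.505 and 0.457, then 0.521 and 0.557.

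**Figure D3:**
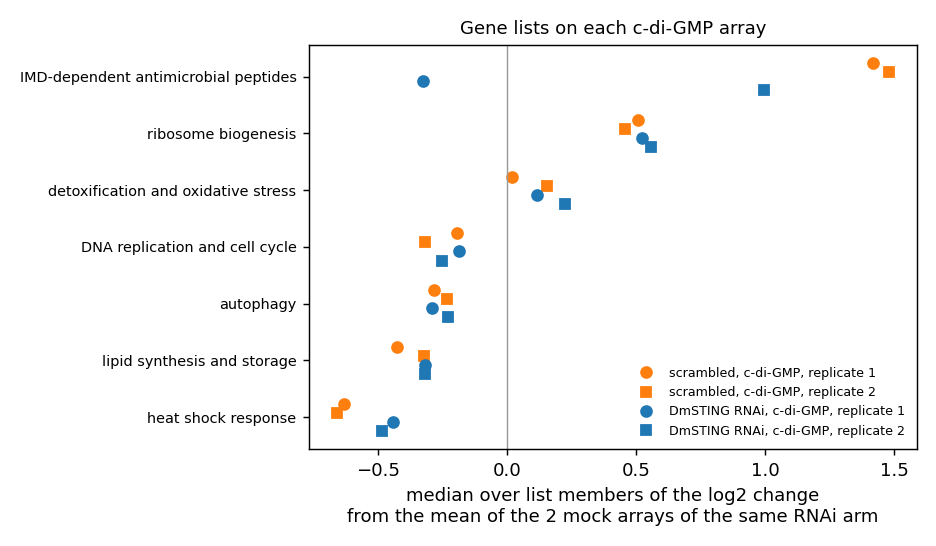
Median log2 change of gene lists in each c-di-GMP sample from the mean of the mock samples of its arm. Antimicrobial peptides lie at 1.417 and 1.479 in the scrambled samples and at -0.325 and 0.993 in the DmSTING RNAi samples, while ribosome biogenesis lies between 0.457 and 0.557 in all 4.

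Over all genes limma called 0 for the interaction, with 540 at an unadjusted p under 0.05 where 550 would be by chance and a smallest adjusted p of 0.988. The genes of smallest p were CG15740 at 0.7, CG13577 at 0.71, CG14961 at 0.57, Tssk at 0.74 and CG13358 at 0.57, and CG18234 at -0.85, CG10086 at -0.94, Ir40a at -0.53, CG8630 at -0.68 and Grl36a at -0.57, none past the threshold. Sting stood at -0.02 (SE 0.1). Without DmSTING RNAi c-di-GMP replicate 2, 12 genes were called. The other 24 lists had adjusted p between 0.0607, for the unfolded protein response, and 0.934. A second list was called without scrambled mock replicate 2, with quantile normalization, with arrays centred on their medians and with the highest-mean probe set, and 3 lists without DmSTING RNAi c-di-GMP replicate 2.

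Without c-di-GMP, DmSTING RNAi lowered the Sting transcript and no other gene passed. Sting changed by -1.29 (SE 0.07, n = 2 per group, 41% remaining, adjusted p = 0.0032), and was the only call among 355 genes at an unadjusted p under 0.05. Rph at 0.55 and bug at -0.6 (adjusted p = 0.996) did not pass, nor did CecB at -0.32, and the antimicrobial peptide list stood at -0.01 (adjusted p = 0.928). None of the 25 lists was called (adjusted p from 0.474 to 0.982). The Sting call was lost without any 1 of the 4 libraries compared (adjusted p from 0.096 to 0.113, changes from -1.27 to -1.3).

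With c-di-GMP, DmSTING RNAi again left Sting as the only gene called, at -1.31 (SE 0.07, n = 2 per group, 40.3% remaining, adjusted p = 0.00281). At an unadjusted p under 0.05 stood 1511 genes, where 550 would be by chance on average. Such counts vary widely when genes are not independent, so further changes are neither shown nor excluded. Antimicrobial peptides were lower than in scrambled c-di-GMP samples, at a median of -1.07 (camera adjusted p = 9.3e-05; adjusted p = 0.506 with an estimated correlation and 0.417 by fry), with all 6 members negative. Of these 0 passed over all genes and 1 adjusted over the list alone. Mtk stood at -1.6 (adjusted p = 0.287) and Def at -1.81 (adjusted p = 0.31). Without DmSTING RNAi c-di-GMP replicate 1 they stood at -0.8 and -0.72, and without replicate 2 at -2.4 and -2.9, each resting on the 1 sample left in that group. That list median was -0.29 without DmSTING RNAi c-di-GMP replicate 1, -1.86 without replicate 2, and -0.65 after quantile normalization.

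Camera called 4 more lists there, each with an adjusted p = 0.506 with an estimated correlation. Cytosolic ribosomal proteins stood at 0.08, positive in 37 of 41 (adjusted p = 0.0168), and the unfolded protein response at -0.07, negative in all 9, neuronal markers at -0.07, negative in 6 of 8, and detoxification genes at 0.14, positive in 13 of 17 (adjusted p = 0.0373 each). Over all genes none of their members passed, and adjusted over the list alone 4 detoxification genes did, all higher. The calls for ribosomal proteins and the unfolded protein response ended without either scrambled c-di-GMP replicate or DmSTING RNAi c-di-GMP replicate 1, that for detoxification without either scrambled c-di-GMP replicate or DmSTING RNAi c-di-GMP replicate 2, and that for neuronal markers without replicate 1 of either c-di-GMP group and with quantile normalization. The other 20 lists had adjusted p between 0.061 and 0.92.

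Genes of smallest p under c-di-GMP included CG15740 at 0.76 (adjusted p = 0.209), SPARC at 0.72, CG14629 at 0.57, CG15343 at 0.54, CG14961 at 0.51, spirit at -0.76, CG10086 at -0.75, Fie at -0.54 and Tsp96F at -0.52 (adjusted p = 0.236), none past the threshold. The Sting call under c-di-GMP was lost after quantile normalization (-1.09, adjusted p = 0.0818) and without DmSTING RNAi c-di-GMP replicate 1 (-1.26, adjusted p = 0.0632), and 34 genes were called without replicate 2. When only the 4 libraries compared were fitted, limma called 0, with 847 at an unadjusted p under 0.05.

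Averaged over both arms, c-di-GMP changed 2304 of the 11009 genes, 842 higher and 1462 lower, of which 12 and 21 changed at least 2-fold. The highest were CG8519 at 1.74, Mtk at 1.61 (SE 0.31, n = 2 per group, adjusted p = 0.0106), Tret1-1 at 1.57 (SE 0.07, adjusted p = 0.000177), CG32373 at 1.5, CG3348 at 1.28, CG34165 at 1.24, CG43109 at 1.2, Ugt302K1 at 1.18, CG34227 at 1.14 and Tdh at 1.05. For Mtk, CG8519, CG32373, CG34165, CG43109 and CG34227, in that order, these means pool samples that differed. In DmSTING RNAi c-di-GMP replicate 1 they stood at 0.01, -0.1, -0.17, -0.08, -0.2 and -0.04 relative to the arm's mock mean, and in replicate 2 at 1.61, 1.76, 1.52, 1.23, 1.44 and 1.07. Without replicate 2 of that group CG43109 averaged 0.79 (adjusted p = 0.00835). The lowest were btn at -2.2 (SE 0.11), CG6770 at -1.91, CAH1 at -1.77, Drat at -1.69, Gs1 at -1.53, mlt, CAH2 and BNIP3 at -1.49, dnr1 at -1.43 and CG11658 at -1.37. Nazo rose by 0.85 (adjusted p = 0.00501). Plasmatocyte markers that fell were NimC1 by 0.6, vkg by 0.45, Col4a1 by 0.35 and crq by 0.34. The means of vkg and Col4a1 pool unlike values: vkg stood at -0.95 and -0.52 in the scrambled c-di-GMP samples and at -0.14 and -0.18 in those of DmSTING RNAi, and Col4a1 at -0.72 and -0.5, then -0.07 and -0.11, with neither interaction called (adjusted p = 0.988 each). The call of vkg was lost without scrambled mock replicate 2, either DmSTING RNAi mock replicate or DmSTING RNAi c-di-GMP replicate 2, that of crq without scrambled mock replicate 2 or DmSTING RNAi mock replicate 1, and that of Col4a1 without DmSTING RNAi mock replicate 2 (adjusted p from 0.0504 to 0.0719).

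Camera called 8 lists for the average effect. Counts of members past the threshold are over all genes, then adjusted over the list alone. Ribosome biogenesis rose (16 of 18, then 16 with 1 falling, median 0.51, adjusted p = 1.39e-14; adjusted p = 0.0432 with an estimated correlation). Lipid genes fell (9 of 14, then 9 with 1 rising, median -0.37, adjusted p = 0.000712; adjusted p = 0.327 with an estimated correlation), as did replication genes (9 of 14, then 11 with 1 rising, median -0.27, adjusted p = 0.000712; adjusted p = 0.423 with an estimated correlation), autophagy genes (10 of 16, then 10 with 1 rising, median -0.26, adjusted p = 0.00193; adjusted p = 0.327 with an estimated correlation) and heat shock genes (4 of 6 on both, median -0.59, adjusted p = 0.0144; adjusted p = 0.423 with an estimated correlation). Antimicrobial peptides stood at 0.84, 1 of 6 rising and then 3 (adjusted p = 0.0101; adjusted p = 0.534 with an estimated correlation), and at 0.43 without DmSTING RNAi c-di-GMP replicate 2. Detoxification genes stood at 0.1, 5 rising and 1 falling on both (adjusted p = 0.00425), and small RNA genes at 0.1, 2 of 9 rising on both (adjusted p = 0.0251), each with an adjusted p = 0.423 with an estimated correlation, and the small RNA call ended without DmSTING RNAi mock replicate 2 or DmSTING RNAi c-di-GMP replicate 2. The other 17 lists had camera adjusted p between 0.0685 and 0.955, of which fry called 5: Toll pathway components, JAK-STAT genes, apoptosis and plasmatocyte markers as lower and neuronal markers as higher (adjusted p from 0.0126 to 0.0471). Without DmSTING RNAi mock replicates 1 and 2, 1190 and 1163 genes were called. Of the 81 calls of genes named for the average effect, 24 and 27 were lost without those replicates, and 14 and 21 without scrambled mock replicates 1 and 2. The numbers were 9 and 4 without scrambled c-di-GMP replicates 1 and 2, and 11 and 15 without DmSTING RNAi c-di-GMP replicates 1 and 2. The calls of CG32373 and CG43109 were lost without any 1 of the 4 mock libraries, and that of CG43109 also without either scrambled c-di-GMP replicate and after quantile normalization (adjusted p = 0.0607). The calls of CG8519, CG34165 and CG34227 were each lost without DmSTING RNAi mock replicate 2 and without a scrambled mock replicate, replicate 2 for CG34227 and replicate 1 for the others, and that of CG34165 also without DmSTING RNAi mock replicate 1.

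Averaged over both treatments, Sting was the only gene called for DmSTING RNAi. At an unadjusted p under 0.05 stood 1380 genes, 953 higher and 427 lower, where 550 would be by chance on average. Genes are not independent, and 2-group fits of splits unrelated to treatment or dsRNA gave 137 to 1272. Control transcripts added at hybridization were also higher on the scrambled arrays, by a median of 1.05. Such a difference between arrays cannot be told apart from the knockdown here. Further changes are therefore neither shown nor excluded. CG15482 at 0.56, CG6356 at 0.52, mspo at -0.56, spirit at -0.55, IP3K1 at -0.53 and bug at -0.5 did not pass. Antimicrobial peptides stood at -0.6 (camera adjusted p = 0.0039), cytosolic ribosomal proteins at 0.05, positive in 38 of 41 (adjusted p = 0.0107), and detoxification genes at 0.12 (adjusted p = 0.0389), each with an adjusted p = 0.712 with an estimated correlation. None of their members passed over all genes, and adjusted over the list alone 2 detoxification genes did, both higher. The antimicrobial peptide median was -0.23 without DmSTING RNAi c-di-GMP replicate 1 and -0.93 without replicate 2. After quantile normalization it was -0.32, with the camera call kept. The ribosomal protein call ended without scrambled c-di-GMP replicate 2, and the detoxification call without scrambled mock replicate 2, scrambled c-di-GMP replicate 1, DmSTING RNAi mock replicate 2 or DmSTING RNAi c-di-GMP replicate 2. The other 22 lists had camera adjusted p between 0.0824 and 0.986, of which fry called STING-linked antiviral genes (adjusted p = 0.0491), the list that holds Sting itself, and 12 genes were called without DmSTING RNAi c-di-GMP replicate 2.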

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

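The tests of delivery, of a single library and of the hybridization controls, the set tests without a replicate, and the lists used for growth signalling were chosen only after the data were seen, the last before their own values were; the test of array scaling and the count of splits were not.

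The response of antimicrobial peptides to c-di-GMP differed between the RNAi arms in the test of the difference itself, with a median of -0.92 on the log2 scale (camera adjusted p = 0.000356), a call lost with an adjusted p = 0.768 with an estimated correlation and 0.727 by fry. A complete failure to deliver c-di-GMP in DmSTING RNAi c-di-GMP replicate 1 is argued against. Its ribosome biogenesis genes reached 93.5% of the change in replicate 2 (0.521 against 0.557). Whether that list follows the amount delivered was not tested, so a lower delivery remains open. The size may rest largely on 1 library. Fits without either replicate of this group take its spread from the other groups, so their calls cannot show that a difference holds. The difference between the arms under c-di-GMP was -1.07 with all libraries and -0.29 without DmSTING RNAi c-di-GMP replicate 1. With an estimated correlation and by fry it was not called with all libraries (adjusted p = 0.506 and 0.417) or without that replicate (0.509 and 0.143), while without replicate 2 fry called it (adjusted p = 0.00165) and camera with an estimated correlation did not (adjusted p = 0.0704). An effect of the knockdown, which the design names, and a state of that culture unrelated to it, both remain open, because 2 samples cannot separate them.

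The change shared by both arms was also weighed. Of the 2304 genes called in the average c-di-GMP effect, 95.9% stayed called with the same sign with arrays centred on their medians, and 93.7% after quantile normalization. The array medians lay only between -0.0225 and 0.0079, so centring could hardly change the calls and decides nothing. Quantile normalization argues against a difference in the distribution of array values for the calls it kept. A scaling difference that depends on expression level cannot be seen in centred values and remains open. The real split of the 8 samples into 4 and 4 by treatment called 2185 genes and the highest of the other splits 1 (1 of 35 splits as large). The other splits leave the treatment difference in their spread, which lowers their counts. The replicates may also not be separate cultures, so the count of splits cannot exclude chance differences between cultures. Higher growth signalling of the TORC1 type may contribute, but the lists tested for it do not decide: at a preset inter-gene correlation camera gave RNA polymerase III subunits a median of 0.09 (p = 0.0554) and vacuolar ATPase subunits one of -0.08 (p = 0.16). The transfection itself is common to mock and treated cells, and no inactive nucleotide was among the samples, so an effect of c-di-GMP as such and of any nucleotide delivered remain open.

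The third pattern lies in probe sets outside the comparisons. The control probe set AFFX-Dm-AJ002682-2_s_at, the largest difference of the 49 AFFX-Dm probe sets and singled out for that after the fact, was higher by 2.68 in scrambled than in DmSTING RNAi samples, at 1.48, 1.17, 1.29 and 1.63 against -1.44, -1.37, -1.17 and -1.17. The hybridization controls, 18 probe sets for labelled transcripts added at hybridization, were higher in the same samples, by a median of 1.05, from 0.46 to 1.35. The 2.68 of the first exceeds their largest, 1.35, by 1.33, where their SD was 0.29. That SD is a spread between transcripts and no error of a brightness estimate. Probe sets of bioB differed by 1.19 to 1.35 and those of cre by 0.46 to 0.65. Their range therefore does not bound what brightness could do at another probe set, and the comparison does not decide. What the hybridization controls' own difference comes from was not tested, and the poly-A controls differed by a median of 0.22 over 24 probe sets.

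Of the 4256 probe sets with no gene or several genes, 306 were called in the average c-di-GMP effect, 149 higher and 157 lower.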

How the results depend on the processing

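Robust eBayes was chosen only after the data were seen, as was running the highest-mean probe set, the main choice of the plan, as an alternative; the other settings below were not. Not run were the filter on dim probe sets and the trend, which need an expression level, and the pseudocount, as the values are logarithms; signal over background cannot be read from centred values. In fits without a replicate, the lone sample left is assumed to vary like the other groups. A call in such a fit therefore cannot show that a difference holds where the replicates of that group disagree.

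For c-di-GMP in the scrambled arm (1331 genes) the count was 52 at an unadjusted p under 0.01 with a log2 change of 1, 2165 at an adjusted p under 0.1, 142 with only the libraries compared, and 223 to 1386 with each replicate left out. In the DmSTING RNAi arm (820) it was 22, 1355, 1296 with quantile normalization, and 0 to 1027. The interaction (0) gave 0 to 12, DmSTING RNAi under mock (1) 0 to 1, and its average effect (1) 1 to 12. Under c-di-GMP (1) DmSTING RNAi gave 0 with quantile normalization and with only the libraries compared, 5 at the unadjusted threshold, and 0 to 34. The 0 with quantile normalization stood beside 966 genes at an unadjusted p under 0.05. The average c-di-GMP effect (2304) gave 33 at the unadjusted threshold and 1163 to 2577. A looser or stricter threshold moves a count by construction. Quantile normalization gives the centred values of every array the same spread. Before it, the SD over probe sets was 0.2268 and 0.2124 in scrambled c-di-GMP and 0.1277 and 0.1322 in DmSTING RNAi mock. Its counts and changes therefore include this change of spread, which shrinks the former and enlarges the latter. Fits of only the libraries compared, or without a library outside the comparison, leave its log2 changes as they were. Only the estimate of spread and its degrees of freedom then differ. The scrambled arm thus kept its median change of -0.04 without either DmSTING RNAi mock replicate, where 587 genes were called. For the rest of the change with quantile normalization, and for fits without a library of the comparison, the cause was not tested. The average loss of Sting transcript kept its call in every setting run, at -1.33 to -1.27 with each replicate left out.

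With an estimated correlation the number of lists called was 0 of 9 in the scrambled arm, 1 of 6 in the DmSTING RNAi arm, 0 of 1 for the interaction, 0 of 5 under c-di-GMP, 1 of 8 and 0 of 3 for the average effects of c-di-GMP and of DmSTING RNAi. With fry it was 11 in the scrambled arm, 4 in the DmSTING RNAi arm, 0 for the interaction, 0 under c-di-GMP, and 12 and 2 for the average effects of c-di-GMP and of DmSTING RNAi. The interaction had 2 lists with quantile normalization, centred arrays and the highest-mean probe set, and DmSTING RNAi under mock had 1 with quantile normalization. With each replicate left out the ranges were 5 to 9 in the scrambled arm, 6 to 10 in the DmSTING RNAi arm, 1 to 3 for the interaction, 1 to 8 under c-di-GMP and 2 to 5 for the average DmSTING RNAi effect. Antimicrobial peptides lost their call with an estimated correlation and with fry in the scrambled arm (1.45), the interaction (-0.92) and under c-di-GMP (-1.07). They also lost it with both in the average effects of c-di-GMP (0.84, fry adjusted p = 0.144) and of DmSTING RNAi (-0.6, fry adjusted p = 0.629). In the DmSTING RNAi arm they ranged from -0.32, reversed, to 0.99 with each replicate left out. CecB reversed there without DmSTING RNAi c-di-GMP replicate 2, ranging from -0.25 to 1.83, and under mock without scrambled mock replicate 1, ranging from -0.65 to 0.01. Sting reversed in the DmSTING RNAi arm with quantile normalization, at 0.01, a setting that also changes the spread of each array. Beyond that, the cause of these changes was not tested.

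With replicate block, 10 of 198 calls of named genes were lost. These were Sting (adjusted p = 0.0538), IKKbeta, GNBP3, Fmr1 and bmm in the DmSTING RNAi arm and mys in the scrambled arm. In the average c-di-GMP effect they were key, RpL29, MsrA and elav. The block gave 1386, 786, 0, 1, 1, 2379 and 1 called genes in the 7 contrasts in the order above of scrambled, DmSTING RNAi, interaction, mock, c-di-GMP and the average effects of c-di-GMP and of DmSTING RNAi. Of 990 values of named calls in the other settings 936 kept direction and side of the threshold 53 lost the call and 1 reversed. Of 1584 with a replicate left out, 1130 did and 454 lost it. Of named genes not called, 195 of 195 values in other settings stayed so, and with a replicate left out 299 of 312 did, 11 became called and 2 reversed.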

Other observations

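The signed set test over the responding genes was chosen only after the data were seen, though before its own p was. On average over both arms, several components of the immune pathways fell, while Mtk and Nazo rose. Of all 11009 genes 1462 were called lower. Camera, which compares a list with other genes, called none of the IMD pathway, Toll pathway, JAK-STAT and apoptosis lists. A fall particular to these pathways is therefore not shown. Of 17 IMD pathway genes 4 fell over all genes, and adjusted over the list alone 4 fell and 2 rose (median -0.08, camera adjusted p = 0.298, not called by it), among them Diap2 at -0.48 (SE 0.06) and IKKbeta at -0.29 (SE 0.05). The other calls were less stable: key at -0.15 (adjusted p = 0.0497) was lost in each of the 13 other settings run for it (adjusted p from 0.0521 to 0.182), and imd at -0.19 without any library other than scrambled c-di-GMP replicate 2 (adjusted p from 0.059 to 0.146). Of 13 Toll pathway genes 4 fell, and 7 fell and 1 rose adjusted over the list alone (median -0.2, camera adjusted p = 0.0685, fry adjusted p = 0.0126), with grass at -0.6 (SE 0.06) and the receptor Tl at -0.27 (SE 0.06), whose call was lost without either DmSTING RNAi mock replicate, without DmSTING RNAi c-di-GMP replicate 2 and with the highest-mean probe set. The calls of GNBP3 and Myd88 were also lost without either DmSTING RNAi mock replicate, and that of Myd88 without 4 further libraries (adjusted p from 0.0515 to 0.113). Of 8 JAK-STAT genes 2 fell on both adjustments, vir-1 at -0.64 (SE 0.09) and the cytokine upd2 at -0.27 (SE 0.06), the latter lost without scrambled mock replicates 1 or 2, scrambled c-di-GMP replicate 1, DmSTING RNAi mock replicate 2 or DmSTING RNAi c-di-GMP replicate 2. Of 9 apoptosis genes 4 fell and 1 rose on both, p53 at 0.32 (SE 0.06) being the one that rose (list median -0.12, camera adjusted p = 0.105, fry adjusted p = 0.0471). Of the 120 called genes with several probe sets, 5 had probe sets of opposite sign, RpS7 (0.22) among them.

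Log2 differences between 3' and 5' control probe sets, a sign of RNA quality, were compared between mock and c-di-GMP samples. With centred values they compare samples only and give no ratio within a sample. For GAPDH the log2 difference was 0.09 (SD 0.12) in mock and -0.03 (SD 0.05) in c-di-GMP samples (n = 4 each, two-sided exact permutation p = 0.0571). For eIF-4a it moved the other way, from -0.11 (SD 0.12) in mock to 0.06 (SD 0.1) in c-di-GMP samples (n = 4 each, two-sided exact permutation p = 0.0857). For ACTIN it was 0.02 (SD 0.08) and -0.02 (SD 0.1), with an exact p of 0.543. These permutations exchange all 8 samples without regard to RNAi arm, and the replicates may not be separate cultures. The GAPDH mean in mock also leans on scrambled mock replicate 1, at 0.26, where the other mock samples stood at 0.05, 0.04 and 0.01. A second family of control probe sets was not tested. Its average c-di-GMP effect was -0.01 at the 3' Act5C probe set and -0.17 and -0.15 at the 5' ones. For GAPDH in that family it was -0.17 and -0.18 at 3' and 0.05 at 5'.

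For DmSTING RNAi averaged over both treatments, the real split of the 8 samples into 4 and 4 called 1 gene, and 2 of the 35 splits called at least as many, itself included. The other was the split by treatment, a structure of the samples, which called 2185. By limma the remaining 33 splits called 0, with 137 to 1272 genes at an unadjusted p under 0.05, so no split unrelated to the design gave as many. These splits leave the treatment difference in their spread, which lowers their counts, as it does for the real split by dsRNA. The share of 2 in 35 alone does not exclude chance, and it is the treatment that keeps it there. A count of splits does not ask which gene is called. In the model of 4 groups the gene was Sting, the target of the dsRNA (limma adjusted p = 0.000252). Its values in the 4 samples given DmSTING dsRNA all lay below those in the 4 given the scrambled sequence.

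A response that is smaller after DmSTING RNAi was tested over the 2304 genes called in the average c-di-GMP effect. Their median signed change was 0.35 in the scrambled arm and 0.304 in the DmSTING RNAi arm, and 59.2% had the smaller change in DmSTING RNAi. The signed test of the interaction over these genes with fry, a rotation test that keeps the correlation between genes, gave a two-sided p = 0.0975, at a median of -0.03. The bound written before that p was seen, that a p of 0.05 or more would count against a smaller response, was wrongly framed, since a p that misses the threshold excludes nothing, and the question stays open.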
